A study of Mus musculus with 6 samples.

How the data were processed

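The series labels describe polyA RNA from mouse skin squamous cell carcinoma cells, in 3 groups of 2 libraries named by Itga6 level and CD80. RNA was extracted with a Zymo Quick-RNA Microprep kit and made into libraries with a NEBNext low-input kit, per the labels. The labels do not say how the cells were gated beyond Itga6 and CD80. The table of values used here has columns for 4 libraries, 2 of Itga6hi CD80pos and 2 of Itga6low CD80neg. The group with high Itga6 and no CD80 was not analysed here, so 1 of 3 comparisons set in advance was made.

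Per the submitters' processing notes, the authors used kallisto 0.44.0 and the genome build mm10. The deposited values are TPM per gene, transcript levels scaled to a fixed total, and each column was found to sum to 1000000. The annotation, the summing from transcripts to genes and any filter by the authors are not stated. TPM keep no record of sequencing depth, so the depth of each library is unknown and no interval or detection limit that needs counts is given. A gene listed at 0 is described as listed at 0. The table held 96 spike-in entries, all at 0 in the 4 libraries. Gene identifiers were matched to GENCODE M21 on GRCm38, which held 55144 of them. The table gave no symbol for 3101 identifiers, and 111 had none in either source.

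The choices in this paragraph were made before the data were examined. Genes with at least 1 TPM in at least 2 libraries were tested, 13474 in all. Values were log2(TPM + 1), with no further scaling between libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, at a Benjamini-Hochberg adjusted p under 0.05 and with no fold threshold. The fit had been set for 6 libraries and was made on 4, with 2 residual degrees of freedom and 3.33 prior ones. Lists of genes were tested with limma's camera at an inter-gene correlation of 0.01, in lists with at least 3 tested members, adjusted over 35 lists of the comparison made rather than over all comparisons as set. Camera compares a list with all other tested genes, so a list can be lower than others while its own fold changes lie above 0. Beside it stand camera with an estimated correlation, which gave 0 lists higher and 0 lower where the preset one gave 4 and 18, and fry, which gave 5 and 2 and does not compare a list with other genes. For each list, calls are counted over all genes tested and adjusted over the list alone; these gave the same counts in 20 lists and other counts in 15.

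The gene lists covered basal and stem-like epidermal genes, suprabasal differentiation, stress and wound keratinocyte genes, hemidesmosome and basement membrane, epithelial-mesenchymal transition, epithelial junctions, TGF-beta response, neutrophil-acting cytokines and chemokines, alarmins and antimicrobial genes, lymphocyte-directed chemokines, immune checkpoint and co-stimulatory ligands, MHC class I and class II, interferon response and NF-kB targets. They also covered arachidonic acid and prostanoid genes, fatty acid and cholesterol synthesis, NRF2 and glutathione genes, hypoxia and glycolysis, proliferation, AP-1 and immediate-early genes, heat shock, matrix proteinases, Notch, Wnt, and hair follicle and sebaceous genes. Markers of neutrophils, macrophages and dendritic cells, Langerhans cells, T, NK and B cells, mast cells, fibroblasts, endothelium and pericytes, melanocytes and Schwann cells, muscle and adipocytes, and red blood cells completed them. Sex-linked genes served as a check of libraries. The lists were fixed before the data were examined.

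Named genes followed a rule fixed in advance: Itga6 and Cd80; the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 5 TPM in the higher group, libraries that did not overlap between groups and a symbol that is neither a predicted model nor mitochondrial; up to 4 called members per list by absolute fold change; 2 members by mean TPM where a list was called but no member was; and the member with the highest TPM in any library of each list of other cell types. With Cd74 and H2-Ab1, taken although their list had no call and the rule asked for counts alone, this made 134 tested genes; Fcer1a was under the filter. Some genes given by the rule are not reported here. Any gene named outside it is said to have been chosen after its values were seen, except Ddx3y and H2-Eb1. Ddx3y belongs to the check of libraries, and H2-Eb1 was picked as the MHC class II gene with the lowest unadjusted p. H2ac24 and Pgam1-ps2, a histone gene and a pseudogene with near-identical relatives, were among the highest 8 and are given no values, since reads shared with their relatives were not resolved.

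An exact permutation test of 2 libraries against 2 cannot give a p under 0.333, so none is reported for single genes. The alternatives were other pseudocounts (0.1 and 5), no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling over 9608 genes, quantile normalization, TPM rescaled without 518 mitochondrial, ribosomal protein, haemoglobin and keratin genes, eBayes without a trend or robust, a replicate block, limma treat against a log2 fold change of 0.5, and each library left out in turn. Settings added after seeing the data were TPM rescaled without 12 haemoglobin genes, the calls kept across scalings, camera under 2 of these scalings, and the filter applied again when a library was left out. Where a group kept 1 library, that library is assumed to vary like the other group's.

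The procedure was tested on simulated data with the group sizes and gene levels of this table, in 20 runs with 200 of 13474 genes changed. With each gene's moderated spread as noise, limma recovered 2.62% of genes changed by a log2 of 1, 59.0% at 2 and 98.7% at 4, and 9.06% of its calls were false. With a spread drawn from the fitted prior it recovered 0.0742%, 2.78% and 75.6%, and 5.55% of its calls were false. The noise model was changed after its output was seen, and both are given. The simulated changes were few and went both ways, whereas 7686 genes were called higher and 1277 lower on deposited TPM. The Benjamini-Hochberg adjustment depends on how many genes change, so these rates need not hold for the data. Camera found 20 of 20 lists of 20 genes raised by a log2 of 1.5 and called 0 of the unchanged ones. Noise was drawn for each gene separately, so the simulated genes were uncorrelated. In the data the estimated correlation ranged from -0.274 for Langerhans cell markers to 0.822 for MHC class II genes. The simulation therefore does not measure false calls of camera among lists of correlated genes.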

Results

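The data were bulk RNA sequencing of cells isolated from mouse skin squamous cell carcinomas raised with the carcinogen DMBA and the tumour promoter TPA. The series text compares tumour stem-like cells with differentiated cancer cells. The cells it names stem-like had high Itga6, the integrin alpha 6 chain, and CD80, a co-stimulatory ligand (here Itga6hi CD80pos). The cells it names differentiated had low Itga6 and no CD80 (here Itga6low CD80neg). These names are the submitters' own, and the Itga6low CD80neg libraries also held much RNA of haemoglobin and fibroblast genes. Each population had 2 libraries. Values were TPM, transcript levels scaled to a total of 1000000 in every library, which keep no record of sequencing depth, so the depth is unknown. In the table, 12661 and 12728 genes reached 1 TPM in the Itga6hi CD80pos libraries, and 11982 and 12443 did in the Itga6low CD80neg libraries. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these libraries, whatever its source. Values are given as Itga6hi CD80pos against Itga6low CD80neg, as means ± SD with n = 2 libraries each, and log2 fold changes have the same order.

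The comparison was made to learn how tumour stem cells act on neutrophils. On deposited TPM, 35 of 35 proliferation genes, 24 of 26 hypoxia and glycolysis genes and 18 of 21 epithelial junction genes were higher in Itga6hi CD80pos cells. Lower were 20 of 21 fibroblast genes, 7 of 7 red blood cell genes and 8 of 27 interferon response genes. Of 26 cytokines and chemokines that act on neutrophils, 9 were lower and 7 were higher. As sets these lists passed camera with its preset correlation, and none did with an estimated correlation (adjusted p from 0.446 to 0.672). The estimate rests on 2 residual degrees of freedom, and 0 of all 35 lists passed with it, so failing there tells little about a single list. Proliferation, fibroblast and red blood cell genes passed fry (adjusted p = 0.0334 each). Junction and glycolysis genes (0.0528 each), interferon response genes (0.280) and neutrophil-acting genes (0.393) did not. Fry also placed the basal, lipid synthesis, Notch and Langerhans lists higher (0.0334 each), without comparing them with other genes. Col17a1, the hemidesmosome collagen of basal keratinocytes, stood at 355 ± 175 TPM against 1.76 ± 0.0941 TPM (SD, n = 2). Top2a, a topoisomerase of dividing cells, stood at 79.3 ± 6.17 TPM against 2.94 ± 0.611 TPM. Cxcl12, the ligand of the neutrophil retention receptor Cxcr4, stood at 1.53 ± 0.680 TPM against 245 ± 78.1 TPM, and Il6, an inflammatory cytokine, at 1.81 ± 1.27 TPM against 108 ± 10.8 TPM. Haemoglobin genes made up 0.0124 ± 0.00869% of TPM in Itga6hi CD80pos and 60.7 ± 14.5% in Itga6low CD80neg (SD, n = 2). Keratin genes made up 7.94 ± 0.629% and 1.02 ± 0.713%. A different mix of cells was not separated from a change within tumour cells, for higher or for lower genes.

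**Figure D1:**
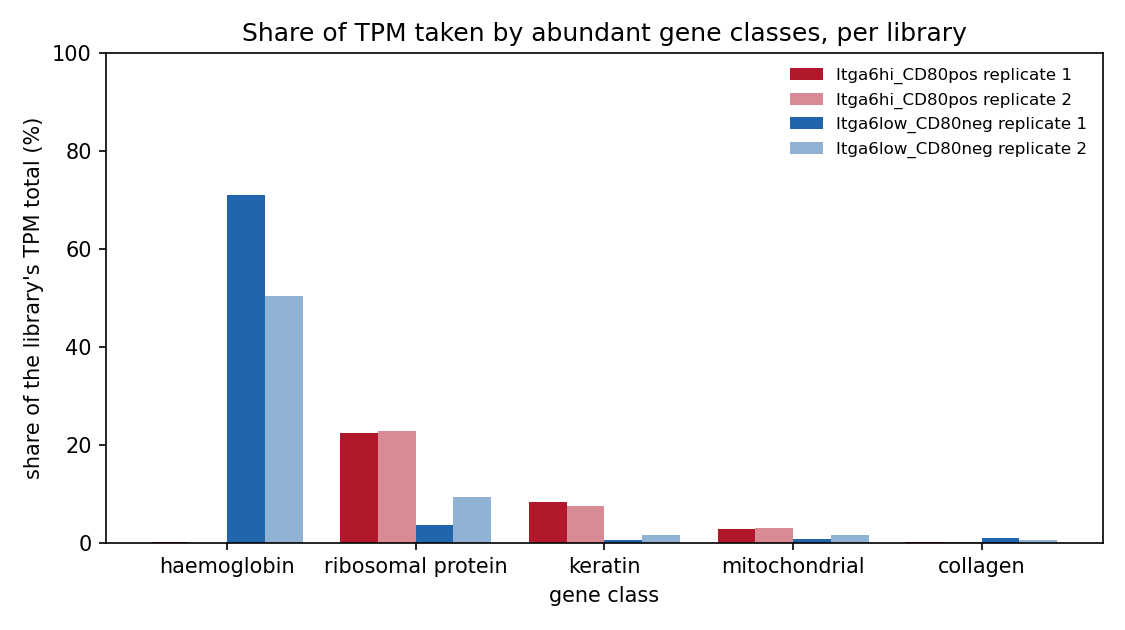
Share of each library's TPM total (y axis, percent) taken by 5 gene classes (x axis), with 1 bar per library, red for Itga6hi CD80pos and blue for Itga6low CD80neg, paler for replicate 2. Haemoglobin genes took 70.9% and 50.4% in the Itga6low CD80neg libraries and 0.0185% and 0.00621% in the Itga6hi CD80pos libraries.

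Of 13474 genes tested with limma, 7686 were higher and 1277 were lower in Itga6hi CD80pos, so 85.8% of the calls were higher. The median log2 fold change of all tested genes was 1.27 on the deposited TPM, and a change is read here relative to that shift. Median-of-ratios scaling moved the median to -0.05 and gave 902 genes higher and 2129 lower. Quantile normalization gave 1448 and 1517, leaving haemoglobin genes out of the TPM total gave 1090 and 1767, and leaving out mitochondrial, ribosomal protein, haemoglobin and keratin genes gave 1906 and 1869. Under each of the 5 scalings that holds the gene, counting the deposited values as 1 of them, 802 genes were higher and 1122 were lower, and these calls are described as kept across scalings. All 5 hold the genes of 788 and 1111 of these calls, since keratin, mitochondrial and ribosomal protein genes are left out of 1 scaling and haemoglobin genes of 2. Leaving haemoglobin alone out of the total, and counting the calls kept, were both chosen after seeing the data. A call kept across scalings can still reflect a different mix of cells, which none of these scalings removes.

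Many calls were lost when either Itga6hi CD80pos library was left out, which leaves the Itga6low CD80neg pair alone to measure spread. Without Itga6hi CD80pos replicate 1, limma called 0 genes higher and 0 lower, although 4442 higher and 1033 lower had an unadjusted p under 0.05. Without its replicate 2, 353 genes were higher and 174 lower, with 5016 and 1120 at an unadjusted p under 0.05. Applying the filter on low values again to the 3 libraries left was a setting chosen after seeing the data. Without either Itga6hi CD80pos library it gave infinite prior degrees of freedom, so every gene got the spread of the trend and its own was ignored. Calls that returned in that setting do not show that single genes were robust. In the same setting the lower calls were 453 without Itga6low CD80neg replicate 1 and 455 without its replicate 2. The 802 and 1122 calls kept across scalings became 0 and 0 when either Itga6hi CD80pos library was left out, or 40 and 441, then 82 and 543, with the filter applied again. They were 1562 higher without Itga6low CD80neg replicate 2, or 1923 with the filter applied again, when the lower ones were 362 and 380 without its replicate 1 and 2. These limits hold for every gene call in the paragraphs that follow: calls were lost for 130 of 134 named genes without Itga6hi CD80pos replicate 1, and for 91 without its replicate 2.

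Itga6 and Cd80, the genes of the markers used to isolate the cells, were both higher in Itga6hi CD80pos. Itga6 (chromosome 2, 71745616 to 71858416, plus strand, GRCm38) stood at 178 and 339 TPM against 1.496 and 1.65 TPM, a log2 fold change of 6.58 ± 0.41 (SE) with adjusted p = 0.00195, kept across scalings. Cd80 (chromosome 16, 38455561 to 38496335, plus strand) stood at 6.24 and 1.89 TPM against 0.642 and 0.563 TPM, a log2 fold change of 1.51 ± 0.48 (SE) with adjusted p = 0.0381. The Cd80 call was lost under each of the other scalings, with adjusted p up to 0.392.

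Genes of the basal layer were mostly higher in Itga6hi CD80pos. Among basal and stem-like epidermal genes, 14 of 20 tested members were higher and 3 were lower, over all genes tested and adjusted over the list alone, and 8 and 1 of these were kept across scalings. The integrin chains Itgb4, at 224 ± 117 TPM against 1.71 ± 1.01 TPM, and Itga3, at 113 ± 93.0 TPM against 0.724 ± 0.0337 TPM, joined Itga6 and Col17a1 among the 8 genes with the highest fold changes. Krt5, the basal keratin, stood at 14182 ± 1590.0 TPM against 304 ± 3.80 TPM, Krt15 at 199 ± 58.1 TPM against 3.29 ± 1.12 TPM and Trp63, the transcription factor of basal keratinocytes, at 127 ± 8.17 TPM against 8.30 ± 4.95 TPM, and all were kept, Krt5 and Krt15 under the 4 scalings that hold keratins (these 3 were chosen after their values were seen). Cd34, a marker of hair follicle stem cells, was chosen in the same way and was lower, at 16.5 ± 13.3 TPM against 83.2 ± 37.6 TPM, as were 20 of 21 fibroblast markers. Sox2, a factor of tumour-initiating cells in this cancer, stood at 29.1 and 0.856 TPM against 0.383 and 0.277 TPM, was under the filter and was chosen in the same way too. The list as a set did not differ from other genes by camera on deposited TPM (adjusted p = 0.304, and adjusted p = 0.672 with an estimated correlation). It was higher than other genes under median-of-ratios scaling (adjusted p = 0.00326) and without haemoglobin genes (adjusted p = 0.00306). A lower share of keratinocyte RNA in Itga6low CD80neg was not separated from a change within keratinocytes.

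Lama3 and Lamb3, laminin chains of the epidermal basement membrane, were higher in Itga6hi CD80pos. Lama3 stood at 73.4 ± 33.6 TPM against 0.925 ± 0.268 TPM and Lamb3 at 92.1 ± 52.2 TPM against 0.444 ± 0.0597 TPM, both kept across scalings. Nid1, a linker protein of the basement membrane that fibroblasts also make, was lower, at 0.748 ± 0.346 TPM against 44.4 ± 40.6 TPM, as were 20 of 21 fibroblast markers. Of 15 hemidesmosome and basement membrane genes, 7 were higher and 5 lower (7 and 6 adjusted over the list alone), and 3 of each were kept. The list's median log2 fold change was -1.20, and camera placed it lower than other genes (adjusted p = 0.0357, and adjusted p = 0.672 with an estimated correlation). That call was lost without Itga6hi CD80pos replicate 1 (adjusted p = 0.190), without Itga6low CD80neg replicate 1 (0.0502), under median-of-ratios scaling (0.779) and without haemoglobin genes (0.612). Epithelial junction genes were higher in 18 of 21 members, over all genes and adjusted over the list alone, and 11 were kept. Dsg3, a desmosome cadherin of the lower epidermis, stood at 134 ± 14.9 TPM against 6.24 ± 3.92 TPM, and the adhesion molecule Epcam at 76.1 ± 28.4 TPM against 3.93 ± 2.46 TPM. Camera placed the junction list higher than other genes (adjusted p = 0.0102, and adjusted p = 0.672 with an estimated correlation). Keratin genes also held a larger share of TPM in Itga6hi CD80pos, so the share of epithelial cells may differ too.

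**Figure D2:**
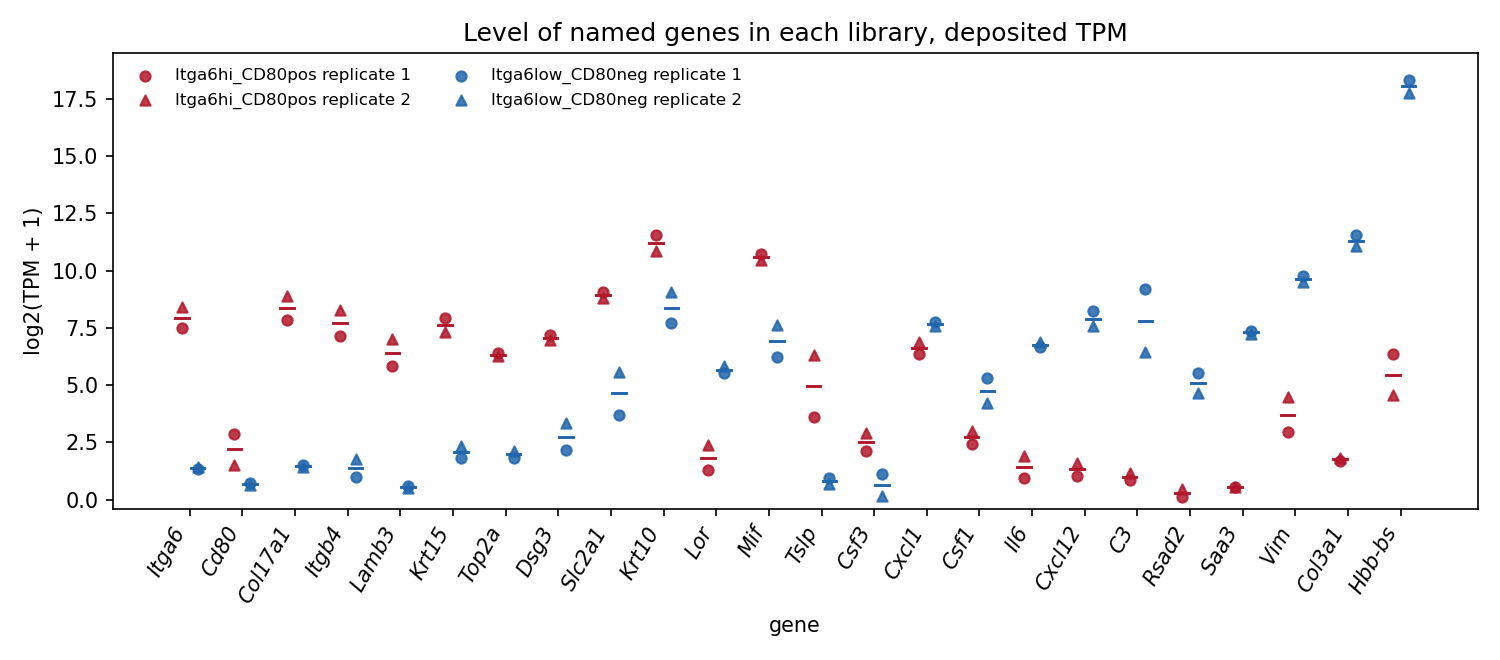
Level of 24 genes in each library, as log2(TPM + 1) on the y axis, with circles for replicate 1, triangles for replicate 2 and a line at each group's mean. Itga6 sits at 178 and 339 TPM in the 2 Itga6hi CD80pos libraries (red) and at 1.496 and 1.65 TPM in the Itga6low CD80neg libraries (blue), and Hbb-bs, a haemoglobin gene, lies the other way round; Krt15, Mif, Tslp, Csf3, Cxcl1 and Csf1 were chosen after their values were seen.

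Genes of the outer epidermal layers went both ways. Lor, the cornified envelope protein loricrin, stood at 2.81 ± 1.92 TPM against 50.4 ± 8.07 TPM and was lower, as was Lce1a1 at 0.319 ± 0.451 TPM against 16.2 ± 2.73 TPM, both kept across scalings. Spink5, a proteinase inhibitor of the granular layer, was higher and kept, at 48.9 ± 21.1 TPM against 4.21 ± 2.07 TPM. Krt10, a suprabasal keratin, was higher on deposited TPM, at 2428 ± 835 TPM against 368 ± 224 TPM, with adjusted p = 0.0227, rising to as much as 0.158 under the other scalings. Of 35 suprabasal differentiation genes, 8 were higher and 4 lower (7 and 4 adjusted over the list alone), and 1 and 4 were kept. Their median log2 fold change was 0.91, under the 1.27 of all genes, and turned to -0.54 under median-of-ratios scaling. Camera placed the list lower than other genes (adjusted p = 0.0339, and adjusted p = 0.672 with an estimated correlation). The call was lost without Itga6hi CD80pos replicate 1 (adjusted p = 0.134), without Itga6low CD80neg replicate 2 (0.224), under median-of-ratios scaling (0.278) and without haemoglobin genes (0.274). Stress and wound keratinocyte genes were higher in 7 and lower in 2 of 19 members (5 and 2 adjusted over the list alone), and of these only the 2 lower calls were kept. Krt6a and Krt17, keratins of wounded epidermis, were higher on deposited TPM, at 13036 ± 2216 TPM against 1566 ± 1070.2 TPM and 3517 ± 1941 TPM against 482 ± 311 TPM. The tissue plasminogen activator Plat was lower, at 0.907 and 1.16 TPM against 47.8 and 52.2 TPM. Reads shared between Krt6a and Krt6b, or within the Sprr2 and Stfa families, were not resolved here. Camera gave the stress list no call (lower, adjusted p = 0.194, and adjusted p = 0.769 with an estimated correlation), although its median and mean lay slightly above those of all genes.

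Proliferation genes were higher without exception on deposited TPM: 35 of 35 members were called, over all genes and adjusted over the list alone, and 30 were kept across scalings. Besides Top2a, the thymidine kinase Tk1 stood at 85.0 ± 18.3 TPM against 3.38 ± 0.609 TPM, the mitotic kinase Plk1 at 38.8 ± 6.12 TPM against 1.13 ± 0.314 TPM and the replication helicase subunit Mcm5 at 78.5 ± 17.4 TPM against 3.67 ± 2.63 TPM. Camera gave adjusted p = 6.15e-07, and adjusted p = 0.657 with an estimated correlation. Hypoxia and glycolysis genes were higher in 24 and lower in 1 of 26 members (25 and 1 adjusted over the list alone), and 9 higher calls were kept. Slc2a1, the glucose transporter GLUT1, stood at 489 ± 56.4 TPM against 29.2 ± 24.3 TPM, the carbonic anhydrase Car12 at 187 ± 27.6 TPM against 5.92 ± 3.98 TPM, Pfkl, a phosphofructokinase, at 189.6 ± 14.7 TPM against 14.6 ± 7.06 TPM and Slc16a3, a lactate exporter, at 99.5 ± 4.42 TPM against 8.74 ± 5.86 TPM. The list was higher than other genes by camera (adjusted p = 0.0122, and adjusted p = 0.672 with an estimated correlation). Whether proliferation and glycolysis genes differed within tumour cells or through the mix of cells was not tested.

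Lipid synthesis and antioxidant genes were also higher, by smaller steps over the median of all genes. Fatty acid and cholesterol synthesis genes were higher in 25 of 26 members, over all genes and adjusted over the list alone, with 4 kept, among them the fatty acid synthase Fasn at 90.9 ± 0.480 TPM against 9.67 ± 1.10 TPM. Camera placed that list higher than other genes (adjusted p = 0.00623, and adjusted p = 0.530 with an estimated correlation). NRF2 and glutathione genes were higher in 22 of 30 members (23 adjusted over the list alone), with 4 kept, among them Nqo1, a quinone reductase, at 108 ± 79.1 TPM against 3.92 ± 1.84 TPM and Gsto1, a glutathione transferase, at 1729 ± 185 TPM against 119.9 ± 86.1 TPM. As a set they passed camera under median-of-ratios scaling (adjusted p = 0.00117), without haemoglobin genes (0.000959) and without Itga6hi CD80pos replicate 2 (0.00476), but not on deposited TPM (adjusted p = 0.0608, and adjusted p = 0.729 with an estimated correlation). Heat shock genes were higher in 10 of 16 members (9 adjusted over the list alone), with Hspd1 and Hspb1 kept, at 236 ± 36.6 TPM against 22.5 ± 8.33 TPM and 1648 ± 451 TPM against 183 ± 39.2 TPM, and had no set call (adjusted p = 0.302, and adjusted p = 0.734 with an estimated correlation).

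**Figure D3:**
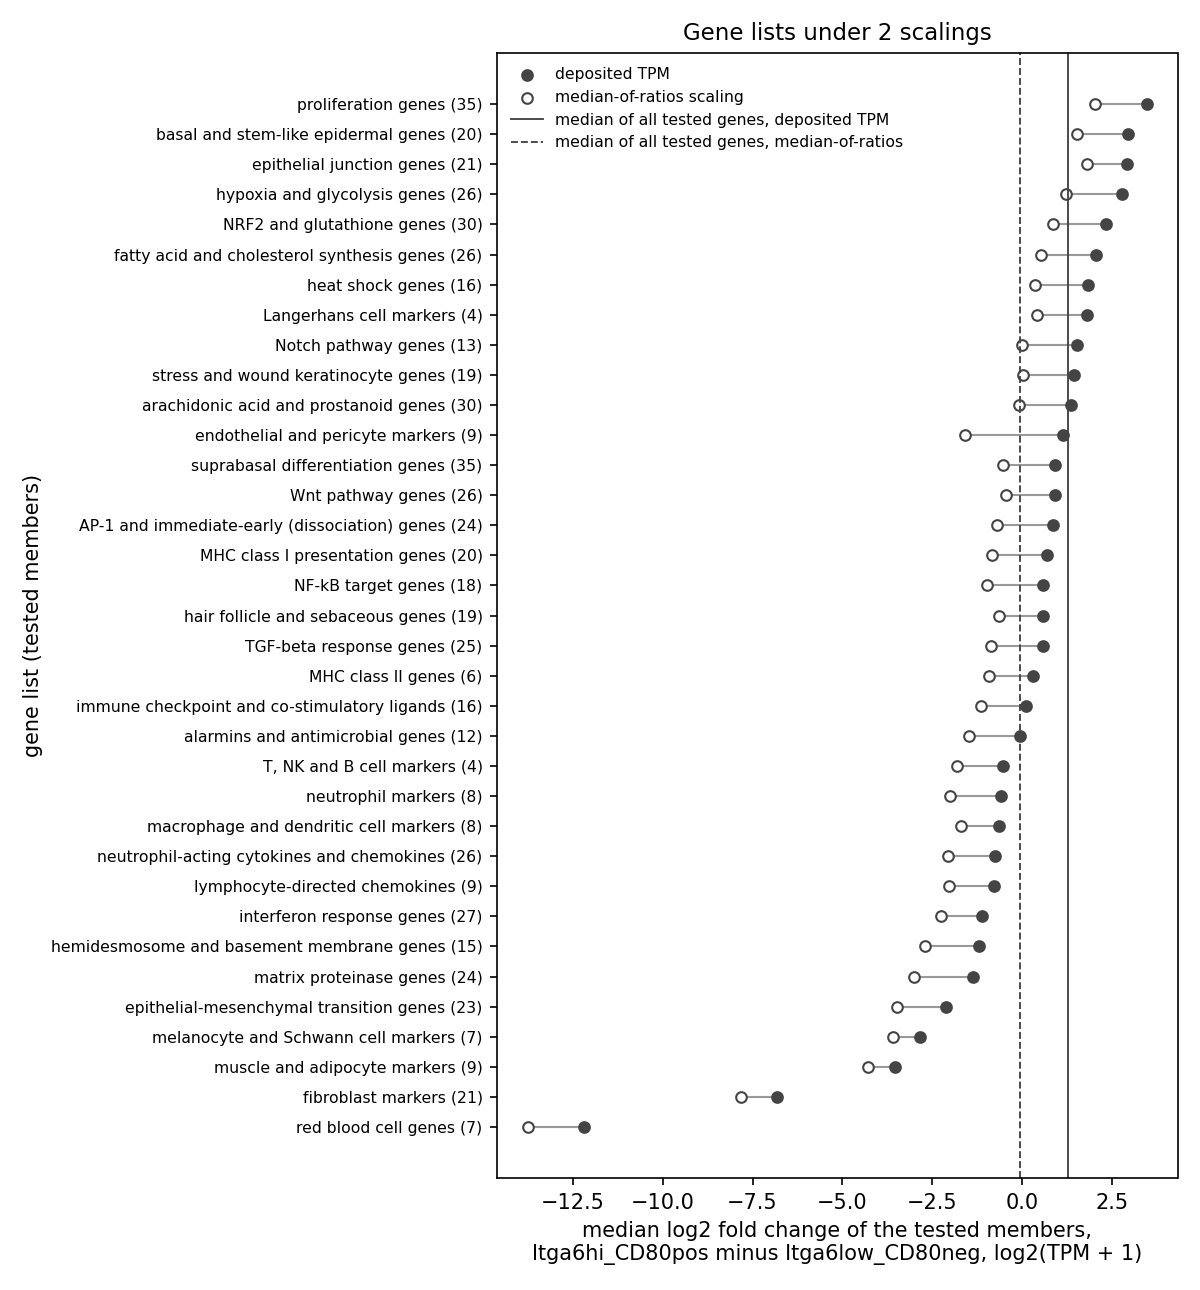
Median log2 fold change of the tested members of each gene list (x axis; number of tested members in parentheses), for deposited TPM (filled) and median-of-ratios scaling (open), with vertical lines at the median of all tested genes, 1.27 and -0.05. Proliferation genes lie highest, at 3.46 and 2.02, and red blood cell genes lowest, at -12.19 and -13.74.

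Cytokines and chemokines that act on neutrophils were more often lower than higher in Itga6hi CD80pos. Of 26 tested members, 9 were lower and 7 higher, over all genes and adjusted over the list alone, and 7 of the lower but only 1 of the higher calls were kept across scalings. C3, the central complement component, was lower, at 0.797 and 1.20 TPM against 584 and 85.4 TPM, a log2 fold change of -6.82 ± 0.90 (SE, adjusted p = 0.00556). Cxcl12 had a log2 fold change of -6.59 ± 0.40 (SE, adjusted p = 0.00185) and Il6 of -5.34 ± 0.42 (SE, adjusted p = 0.00280), both kept. Ccl3, a chemokine of myeloid cells, stood at 0 and 0.156 TPM against 4.403 and 270.3 TPM and was lower on deposited TPM (adjusted p = 0.0459, up to 0.0825 over the scalings). The genes named in the rest of this paragraph were chosen after their values were seen. Il1b, at 0.343 ± 0.163 TPM against 34.4 ± 29.9 TPM, and Csf1, at 5.70 ± 1.88 TPM against 28.0 ± 14.7 TPM, were lower and kept. Cxcl1, Cxcl2 and Cxcl5, ligands of the neutrophil receptor Cxcr2, did not pass on deposited TPM, where the median log2 fold change of all genes was 1.27. Cxcl1 stood at 80.1 and 118 TPM against 217 and 192 TPM (adjusted p = 0.0712), Cxcl2 at 9.02 and 6.81 TPM against 9.39 and 49.9 TPM (0.158) and Cxcl5 at 1.96 and 6.03 TPM against 7.16 and 10.4 TPM (0.1002). Each lay lower in both Itga6hi CD80pos libraries than in both Itga6low CD80neg libraries. Under median-of-ratios scaling 11 members of the list were lower and 1 was higher. Mif, a macrophage migration inhibitory cytokine, was the higher gene that was kept, at 1544 ± 215 TPM against 135 ± 87.1 TPM, a log2 fold change of 3.67 ± 0.66 (SE, adjusted p = 0.00872). Tslp, an epithelial cytokine, was higher at 11.1 and 78.9 TPM against 0.947 and 0.625 TPM, with adjusted p from 0.0129 on deposited TPM to 0.0891 over the scalings. Csf3, the granulocyte colony-stimulating factor, was higher at 3.29 and 6.43 TPM against 1.15 and 0.129 TPM, with adjusted p from 0.0183 to 0.337. Camera placed the list lower than other genes (adjusted p = 1.24e-05, and adjusted p = 0.530 with an estimated correlation). Fibroblast genes, which were lower in 20 of 21 members, moved in the same direction as C3, Cxcl12 and Il6. Myeloid markers moved with Ccl3 and Il1b, highest in Itga6low CD80neg replicate 2: the adaptor Tyrobp stood at 0.103 and 0.162 TPM against 5.68 and 31.5 TPM and the receptor Cxcr4 at 0.374 and 0.462 TPM against 3.12 and 20.8 TPM. Osm, a myeloid cytokine, and Retnlg, a neutrophil marker, were under the filter, at 0 and 0.0710 TPM against 0.946 and 42.6 TPM and 0 and 0 TPM against 0.340 and 9.75 TPM. Camera placed neutrophil markers lower (adjusted p = 0.000568, and adjusted p = 0.509 with an estimated correlation), and macrophage and dendritic cell markers too (adjusted p = 0.0122, and adjusted p = 0.530 with an estimated correlation).

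Alarmins and antimicrobial genes had 3 of 12 members lower, over all genes and adjusted over the list alone, and all 3 were kept across scalings. Saa3, an acute-phase serum amyloid, stood at 0.466 ± 0.00742 TPM against 157 ± 7.97 TPM, and Wfdc12, a proteinase inhibitor, at 0.956 ± 0.245 TPM against 14.4 ± 5.61 TPM. Camera placed the list lower than other genes (adjusted p = 0.000612, and adjusted p = 0.509 with an estimated correlation), a call lost without Itga6low CD80neg replicate 2 (adjusted p = 0.0635). Lymphocyte-directed chemokines were higher in 3 and lower in 3 of 9 members, over all genes and adjusted over the list alone, and the 3 lower calls were kept. Ccl19, a lymphocyte-homing chemokine, and Cxcl13, a B cell chemokine, were lower: Ccl19 was listed at 0 and 0 TPM against 51.9 and 31.3 TPM and Cxcl13 at 0 and 0 TPM against 14.9 and 7.89 TPM. Ccl27a, a skin chemokine, was higher on deposited TPM, at 50.4 ± 35.2 TPM against 8.98 ± 1.18 TPM (adjusted p = 0.0204, up to 0.459 over the scalings). Camera placed the chemokine list lower (adjusted p = 0.0122, and adjusted p = 0.509 with an estimated correlation), a call lost without Itga6hi CD80pos replicate 1 (0.134), under median-of-ratios scaling (0.154) and without haemoglobin genes (0.179). Fibroblast genes, with a median log2 fold change of -6.81, red blood cell genes, lower in 7 of 7, and neutrophil markers as a set moved in the same direction as Saa3, Ccl19 and Cxcl13.

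Interferon response genes were lower in 8 of 27 members (5 adjusted over the list alone), and the 8 were kept across scalings. Under median-of-ratios scaling 14 members were lower and 0 higher. The antiviral protein Rsad2 stood at 0.238 ± 0.201 TPM against 34.5 ± 14.7 TPM, Ifit3 at 0.204 ± 0.185 TPM against 16.3 ± 7.83 TPM and Isg15 at 12.9 ± 6.43 TPM against 62.8 ± 18.1 TPM. Camera placed the list lower than other genes (adjusted p = 4.44e-12, and adjusted p = 0.509 with an estimated correlation). Fibroblast genes, lower in 20 of 21 members, and red blood cell genes, lower in 7 of 7, moved in the same direction. Immune checkpoint and co-stimulatory ligands were higher in 6 and lower in 5 of 16 members, over all genes and adjusted over the list alone, and the 5 lower calls were kept. Entpd1 (CD39) and Cd40 were lower, at 0.748 ± 0.0596 TPM against 8.88 ± 0.0810 TPM and 0.0863 ± 0.00115 TPM against 2.92 ± 1.18 TPM. Nt5e (CD73), like CD39 an enzyme of extracellular adenosine formation, was higher on deposited TPM, at 15.6 ± 6.58 TPM against 2.46 ± 0.801 TPM (adjusted p = 0.00876, up to 0.169 over the scalings). Camera placed the list lower (adjusted p = 0.00623, and adjusted p = 0.462 with an estimated correlation). Of 20 MHC class I presentation genes, Tap1 and Nlrc5 were higher on deposited TPM, with log2 fold changes of 1.48 and 1.28 that turned to -0.03 and -0.046 under median-of-ratios scaling, and neither passed adjusted over the list alone. The list had no camera call on deposited TPM (adjusted p = 0.140, and adjusted p = 0.771 with an estimated correlation). It was lower than other genes under median-of-ratios scaling (0.00941), without haemoglobin genes (0.00448), without Itga6hi CD80pos replicate 2 (0.0119) and without Itga6low CD80neg replicate 1 (0.0344). No MHC class II gene passed limma among 6 tested, and the lowest unadjusted p was 0.0717, for H2-Eb1. Cd74 stood at 5.12 and 38.4 TPM against 4.43 and 20.6 TPM and H2-Ab1 at 16.0 and 17.7 TPM against 5.27 and 23.4 TPM. The MHC class II list had no camera call (adjusted p = 0.102, and adjusted p = 0.672 with an estimated correlation) but was lower without Itga6hi CD80pos replicate 2 (0.0263) or Itga6low CD80neg replicate 1 (0.00665). NF-kB target genes were higher in 8 and lower in 1 of 18 members (3 and 1 adjusted over the list alone), and the lower Vcam1, at 0.408 ± 0.0730 TPM against 7.74 ± 3.24 TPM, was kept. They had no camera call (adjusted p = 0.132, and adjusted p = 0.672 with an estimated correlation) except without Itga6hi CD80pos replicate 2 (lower, 0.0231).

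Fibroblast and mesenchymal genes were mostly lower in Itga6hi CD80pos. Fibroblast markers were lower in 20 of 21 members, over all genes and adjusted over the list alone, and all 20 were kept across scalings. Col3a1, a fibrillar collagen, stood at 2.39 ± 0.238 TPM against 2543 ± 594 TPM, Col1a2 at 1.96 ± 0.110 TPM against 1639.7 ± 662 TPM and the proteoglycan Dcn at 1.18 ± 0.122 TPM against 1010.1 ± 107 TPM, and camera gave adjusted p = 4.44e-32, and adjusted p = 0.446 with an estimated correlation. Epithelial-mesenchymal transition genes were lower in 14 and higher in 4 of 23 members, over all genes and adjusted over the list alone, and the 14 lower calls were kept. Vim, the filament protein vimentin, stood at 14.0 ± 10.4 TPM against 789.6 ± 93.6 TPM, Tagln at 1.41 ± 0.0729 TPM against 222 ± 88.2 TPM and Twist2, a mesenchymal transcription factor, at 0.0391 ± 0.0553 TPM against 30.7 ± 6.89 TPM, with camera adjusted p = 4.44e-12, and adjusted p = 0.446 with an estimated correlation. Matrix proteinase genes were lower in 11 and higher in 7 of 24 members, over all genes and adjusted over the list alone, with 11 and 2 kept. Ctsk, a collagen-degrading cathepsin, stood at 0.404 ± 0.126 TPM against 463 ± 193 TPM and Mmp2, a gelatinase, at 13.3 ± 8.37 TPM against 301 ± 142 TPM, with camera adjusted p = 6.15e-07, and adjusted p = 0.446 with an estimated correlation. TGF-beta response genes were higher in 6 and lower in 4 of 25 members on deposited TPM (4 and 3 adjusted over the list alone), but 0 were higher and 8 lower under median-of-ratios scaling. The 4 lower calls were kept, among them Col1a1, which is also a fibroblast marker, and Ccn2 at 1.39 ± 0.859 TPM against 80.2 ± 13.7 TPM. Tgfbi was higher on deposited TPM, at 291 ± 56.9 TPM against 44.7 ± 21.2 TPM (adjusted p = 0.00865, up to 0.0655 over the scalings). The TGF-beta list was lower than other genes (adjusted p = 0.00676, and adjusted p = 0.509 with an estimated correlation).

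Markers of cell types other than keratinocytes were measured in both populations. All 7 red blood cell genes were lower, over all genes and adjusted over the list alone, and were kept, the 4 haemoglobin genes among them under the 3 scalings that hold these. Hbb-bs, the adult beta globin, stood at 51.7 ± 41.5 TPM against 275409 ± 74664 TPM and the haem synthesis enzyme Alas2 at 0.451 ± 0.0854 TPM against 1415 ± 517 TPM, with camera adjusted p = 7.89e-13, and adjusted p = 0.446 with an estimated correlation. Reads shared between Hba-a1 and Hba-a2, or Hbb-bs and Hbb-bt, were not resolved here. Muscle and adipocyte markers were lower in 8 and higher in 1 of 9 members, over all genes and adjusted over the list alone, with the 8 kept. The muscle actin Acta1 stood at 0.0151 ± 0.0213 TPM against 27.0 ± 18.7 TPM, whereas Fabp4, the fatty acid binding protein with the highest level on that list, was higher on deposited TPM at 1039 and 348 TPM against 104 and 184 TPM, with adjusted p from 0.0434 to 0.539 over the scalings (camera adjusted p = 1.16e-09, and adjusted p = 0.473 with an estimated correlation). Melanocyte and Schwann cell markers were lower in 5 and higher in 1 of 7 members, over all genes and adjusted over the list alone, with 3 lower calls kept. Dct, an enzyme of melanin synthesis, stood at 0.245 and 0.427 TPM against 14.8 and 53.3 TPM (camera adjusted p = 0.000297, and adjusted p = 0.446 with an estimated correlation).

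Few immune cell markers reached 1 TPM in 2 libraries, and several stood above it in Itga6low CD80neg replicate 2 alone. Gzmb, a granzyme of cytotoxic lymphocytes, stood at 0 and 0.0238 TPM against 0.0354 and 18.2 TPM, the Fc receptor Fcgr3 at 0 and 0 TPM against 0.655 and 6.18 TPM and Ms4a2, a mast cell receptor chain, at 0 and 0 TPM against 0.0265 and 3.07 TPM (chosen after their values were seen). Among neutrophil markers, 8 of 21 passed the filter and 2 were lower (1 adjusted over the list alone), with Il1r2, a decoy receptor for interleukin 1, kept at 3.97 ± 0.841 TPM against 15.1 ± 5.06 TPM. S100a9, which neutrophils and stressed keratinocytes both express, stood at 610.5 and 409.5 TPM against 363 and 1588 TPM and did not pass (adjusted p = 0.557). It passed as lower under quantile normalization and without Itga6low CD80neg replicate 1, and its direction turned without replicate 2. Macrophage and dendritic cell markers were lower in 3 and higher in 1 of 8 tested members, over all genes and adjusted over the list alone, and the 3 lower calls were kept, among them the signalling adaptor Tyrobp at 0.132 ± 0.0422 TPM against 18.6 ± 18.2 TPM. Apoe, which keratinocytes express too, was the most abundant member, at 1429 and 3452 TPM against 383 and 808 TPM. T, NK and B cell markers had 4 tested members, of which Ptprc and Trac were lower and kept and Trbc2 was higher on deposited TPM, at 142 and 93.1 TPM against 10.6 and 34.9 TPM, over all genes and adjusted over the list alone. Their camera call (lower, adjusted p = 0.0435, and adjusted p = 0.661 with an estimated correlation) was lost without Itga6hi CD80pos replicate 2 (0.0655), without Itga6low CD80neg replicate 2 (0.0671) and under median-of-ratios scaling (0.146), but not without haemoglobin genes (0.0162). Of 4 tested Langerhans cell markers, Epcam, which is also on the junction list, and Fscn1 were higher, at 229 and 207 TPM against 36.4 and 20.8 TPM for Fscn1, over all genes and adjusted over the list alone, with Epcam kept. That list had no camera call (lower, adjusted p = 0.984, and adjusted p = 0.986 with an estimated correlation), with its median and mean above those of all genes. Endothelial and pericyte markers were higher in 3 and lower in 3 of 9 members (4 and 3 adjusted over the list alone), with 2 lower calls kept. Egfl7, an endothelial gene, was higher on deposited TPM, at 10.4 and 9.95 TPM against 0.873 and 1.47 TPM (adjusted p = 0.00523, up to 0.0529 over the scalings). Eng, an endothelial receptor, was lower at 1.51 and 2.12 TPM against 19.3 and 6.69 TPM, and the list had no camera call (adjusted p = 0.103, and adjusted p = 0.661 with an estimated correlation) except without Itga6low CD80neg replicate 2 (lower, 0.0413). No mast cell marker passed the filter, and Fcer1a, the highest, was listed at 0 and 0 TPM against 0 and 3.35 TPM.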

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

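Leaving out haemoglobin genes, the filter applied again, the calls kept across scalings and camera under median-of-ratios scaling or without haemoglobin genes were chosen after seeing the data; the other settings were set before. Counts of genes higher and lower stayed within 1.5 times 7686 and 1277 under pseudocounts of 0.1 (7314 and 1225) and 5 (7884 and 1240), without a trend (7687 and 1235), with robust eBayes (7756 and 1296), against a log2 fold change of 0.5 (5528 and 969) and with a replicate block (8044 and 1452). The shared replicate numbers have no stated meaning, and the fit without pairing was set in advance. Deviations of same-numbered libraries correlated at 0.109 across genes, which are not independent replicates, so this value does not show whether libraries were paired. With no filter, 4564 were higher, as 30663 genes were tested; with a mean of at least 5 TPM, 613 were lower, of 8821 tested. The scalings changed the split: median-of-ratios gave 902 higher and 2129 lower, quantile 1448 higher, no haemoglobin genes 1090 and no abundant classes 1906 higher. Without 1 library, higher calls ranged from 0 to 8227 and lower ones from 0 to 1237, or from 2947 to 8386 and from 453 to 931 with the filter applied again. Calls kept across scalings ranged from 0 to 1562 higher and from 0 to 1222 lower, or from 40 to 1923 and from 362 to 543 with the filter applied again. With 3 libraries, 1 residual degree of freedom is left. With the filter applied again and an Itga6hi CD80pos library left out, the prior degrees of freedom were infinite. Those counts thus rest on the spread of the trend and not on each gene's own. The cause of the lost calls was not tested further. Lists by camera were 4 higher and 18 lower, but 0 and 0 with an estimated correlation; fry gave 2 lower. Median-of-ratios scaling gave 6 and 14, no haemoglobin genes 6 and 15; a replicate block gave 6 and 15; without 1 library they ranged from 4 to 5 and from 15 to 20. Of 134 named genes, 102 were the same and 27 weaker under median-of-ratios scaling, and 134 were the same with the replicate block. The direction was reversed for Cd74 (0.52): -0.88 under median-of-ratios, -0.60 under quantile, -0.76 without haemoglobin genes, -0.54 without abundant classes, -0.82 without Itga6hi CD80pos replicate 2 and -0.48 without Itga6low CD80neg replicate 1, although 1.87 without Itga6hi CD80pos replicate 1. It was also reversed for H2-Ab1 (0.53): -0.92, -0.67, -0.77, -0.53 and, without Itga6low CD80neg replicate 1, -0.45; for Nlrc5, -0.046, and Tap1, -0.034, under median-of-ratios; and for S100a9 (-0.60), 0.46 without Itga6low CD80neg replicate 2, against -1.67 without its replicate 1. Under median-of-ratios scaling Cd74, H2-Ab1, Nlrc5 and Tap1 moved about as far as the median of all genes, which went from 1.27 to -0.05; for the other reversals the cause was not tested. A fit of the compared groups alone is the fit reported, and the libraries not analysed here were not left out in turn.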

Other observations

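Members of the Notch, Wnt and arachidonic acid lists also differed between the populations. Jag2, a Notch ligand, stood at 55.3 ± 7.15 TPM against 0.282 ± 0.140 TPM and Nrarp, a Notch target, at 104 ± 44.7 TPM against 9.72 ± 5.18 TPM, both kept across scalings. Of 13 Notch pathway genes, 7 were higher and 2 lower, over all genes and adjusted over the list alone, and 2 and 1 were kept, with no camera call (adjusted p = 0.846, and adjusted p = 0.858 with an estimated correlation). Of 26 Wnt pathway genes, 12 were higher and 6 lower, over all genes and adjusted over the list alone, and 4 and 6 were kept. Wnt10a was higher, at 39.6 ± 18.1 TPM against 1.65 ± 1.43 TPM, whereas the secreted Wnt inhibitor Wif1 was lower, at 0.487 ± 0.277 TPM against 39.8 ± 2.73 TPM, as was Sfrp2, which is also a fibroblast marker. The Wnt list was lower than other genes by camera (adjusted p = 0.0122, and adjusted p = 0.462 with an estimated correlation), a call lost without Itga6hi CD80pos replicate 2 (0.0517), under median-of-ratios scaling (0.547) and without haemoglobin genes (0.493). Of 30 arachidonic acid and prostanoid genes, 15 were higher and 4 lower (15 and 3 adjusted over the list alone), with 1 and 3 kept. The cyclooxygenase Ptgs1 was higher and kept, at 45.6 ± 10.1 TPM against 4.71 ± 0.194 TPM, and Ptgds, a prostaglandin D synthase, was listed at 0 and 0 TPM against 5.02 and 19.9 TPM. That list had no camera call (lower, adjusted p = 0.822, and adjusted p = 0.858 with an estimated correlation), with its median and mean slightly above those of all genes.

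Hair follicle and sebaceous genes were higher in 7 and lower in 3 of 19 members (7 and 1 adjusted over the list alone), with 2 of each kept, the keratins under the 4 scalings that hold them. Krt79, a keratin of the sebaceous duct, was higher, at 196 ± 108 TPM against 14.3 ± 2.34 TPM, and Krt75, a hair follicle keratin, was lower, at 2.06 ± 1.26 TPM against 16.5 ± 2.16 TPM. The list had no camera call (lower, adjusted p = 0.103, and adjusted p = 0.672 with an estimated correlation) except without Itga6low CD80neg replicate 1 (0.0322). AP-1 and immediate-early genes, which tissue dissociation also induces, were higher in 6 and lower in 1 of 24 members, and in 2 and 0 adjusted over the list alone. Fosl1, an AP-1 subunit, was higher and kept, at 92.1 ± 2.99 TPM against 5.96 ± 0.419 TPM, and Klf2 was lower and kept, at 13.3 ± 10.6 TPM against 60.9 ± 28.1 TPM, with no camera call (lower, adjusted p = 0.573, and adjusted p = 0.729 with an estimated correlation). Xist, expressed from the inactive X chromosome, stood at 20.7 and 10.3 TPM against 13.9 and 10.8 TPM, and the Y-linked Ddx3y at 0.161 and 0 TPM against 0 and 0.313 TPM.

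The tests of the haemoglobin share, of spike-in entries, of a mesenchymal state and of basal against suprabasal genes were chosen after the result was seen; the further gene lists were written after the pattern, but before the values of their genes were seen, to replace a circular test on the markers already called, whose value had been seen. Most calls were higher in Itga6hi CD80pos on the deposited TPM. With 12 haemoglobin genes left out of the total, which scales every other gene of a library by the same factor, 38.15% of calls were higher, not 85.75%. That value follows from haemoglobin shares seen before, so it is no evidence of its own for a few genes taking most of the Itga6low CD80neg total as the cause. Genes other than haemoglobin held 29.07% and 49.62% of TPM in the Itga6low CD80neg libraries, against 99.98% and 99.99% in the Itga6hi CD80pos libraries. Without haemoglobin genes the median log2 fold change was 0.08, not 1.27. By this arithmetic the haemoglobin share accounts for most of the median shift in TPM. Every library sums to 1000000 TPM, so more RNA per cell, alike for all genes, would not move TPM. Whether Itga6hi CD80pos cells held more RNA of most genes stays open, and the 96 spike-in entries, all at 0, do not decide it.

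Red blood cell, fibroblast, muscle and melanocyte genes were lower in Itga6hi CD80pos. Of 17 tested genes on a further list of red blood cell genes, 70.59% were lower in both Itga6hi CD80pos libraries, against 12.07% of other genes (Fisher's exact test, p = 3.41e-08, over genes, which are not independent replicates), although 4 were called higher. Of 29 tested genes on a further fibroblast list, 96.55% were lower, against 11.96% (Fisher's exact test, p = 4.80e-25). RNA of red blood cells and fibroblasts in the Itga6low CD80neg libraries may therefore account for part of the pattern, and no gate beyond Itga6 and CD80 that would remove such cells is stated in the labels. A mesenchymal state of the tumour cells themselves stays open for the fibroblast genes, since their summed level, up to 12470 TPM in an Itga6low CD80neg library, does not say which cells held them.

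Suprabasal genes differed less between the populations than basal genes. The medians of 19 basal genes, without Itga6, and of 35 suprabasal genes were 2.83 and 0.91, a difference of 1.92 on the log2 scale (permutation test with 100000 resamples of genes, p = 0.00104, two-sided), from 0.97 to 2.77 over 4 pairs of libraries. It was 2.06 under median-of-ratios scaling and 2.07 without haemoglobin genes. Both scale each library by 1 factor, which alters this difference only through the pseudocount, so they are no further evidence. Dilution of the same epithelial cells by other RNA that holds genes of neither list would move both lists about alike. However, the cells were sorted on Itga6, itself on the basal list, so a larger difference in basal genes was favoured in advance. The other RNA may also hold genes of these lists, so the test does not decide about dilution. Its p-value is over genes, which are not independent replicates. A more differentiated state of the keratinocytes in Itga6low CD80neg may be part of the difference, as a hypothesis found and tested on the same data, and a different mix of epithelial cells was not separated from it.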
